A study of Homo sapiens with 52 samples.

How the data were processed

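RNA was measured in soma and neurite fractions of i3Neurons in 52 libraries: untreated neurons (4 per fraction), an HNRNPA1 knockdown experiment (6 knockdown and 6 non-targeting libraries per fraction) and a TDP-43 knockdown experiment (5 of each per fraction). Groups were taken from the sample titles. Per the labels' protocols, libraries were made from 10 ng of RNA with a total RNA kit, in version 2 for untreated cells and version 3 for the knockdown experiments, so kit version cannot be told apart from experiment. Numbered samples exist in each group, but the labels do not say whether they are separate cultures.

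The deposited table holds expected counts, 1 value per gene and library, for 63241 genes. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.7.11b and counted with featureCounts of Subread 2.0.6. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Of the nonzero values 81.1% are whole numbers (within 0.005) and the others are fractional, so some reads were divided between genes in the deposited counts, by overlap or by mapping to several places. The counts were rounded to whole numbers for the tests here. Gene names came first from a list of names that held 62666 of the gene identifiers, and where it gave none from GENCODE release 29. Types, strands and positions came from GENCODE release 29, which held 58228 of the gene identifiers. For the others the type came from RefSeq by name, where it was found. CPM are the counts divided by TMM-scaled library sizes, per 1e6.

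TDP-43 knockdown soma sample 5 held 541 counts in all and was left out, under the limit of 100000 counts. Libraries from the same group were compared in 108 pairs for copies, by the chi-square of their counts per degree of freedom over genes with at least 20 counts, which ran from 1.91 to 161.3, and none was a copy. With 200 genes changed in simulated counts like those of the TDP-43 soma comparison, the tests found 82.1% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes. In counts like those of untreated cells they found 31.3, 62.7 and 86.4%. Genes with the lowest mean CPM were never among the changed ones, so these shares do not cover them. Calls in error made up 4.76 and 5.51% of the calls in these simulations. In those of the other contrasts they ran from 2.8% (TDP-43 interaction) to 8.05% (difference between knockdowns in soma).

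Each experiment was fitted on its own with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter, 1 coefficient per group and quasi-likelihood F tests. Contrasts were neurites against soma in untreated cells and in each set of controls, knockdown against control in each fraction, and the interaction of knockdown and fraction. A second edgeR fit of both knockdown experiments gave the difference between knockdown effects, and a further fit of untreated and control libraries the difference in neurite to soma ratio. Tests are 2-sided and p-values were adjusted by Benjamini and Hochberg over the genes of each contrast, with calls at adjusted p under 0.05. A log2 value is followed by ± its standard error from the fit, and a CPM or percent by ± the standard deviation of its group.

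Sets of 31 gene lists, written down before the data were examined, were tested with camera of limma 3.58.1. This test asks whether a list's genes rank higher or lower than all other genes, with a preset correlation of 0.01 between genes, and its p-values were adjusted over the lists of a contrast. The same test with the correlation estimated from the residuals, and fry, a rotation test of the list on its own, served as alternatives. Counts of list members adjusted over the list alone use the p-values of the members only. The lists are cytosolic ribosomal proteins, translation factors, mitochondrially encoded proteins, nuclear-encoded respiratory chain, mitochondrial ribosomal proteins, proteasome, glycolysis, nuclear-retained noncoding RNAs, neuronal transcription factors, axonal cytoskeleton and growth, motors, presynaptic, dendritic and postsynaptic genes, voltage-gated channels, genes with cryptic splicing after TDP-43 loss, hnRNP proteins, SR splicing factors, RNA granule and transport proteins, the unfolded protein and integrated stress response, endoplasmic reticulum translocation and secretion, cholesterol synthesis, autophagy and lysosome, p53 targets, immediate early and axon injury genes, interferon-stimulated genes, nuclear pore and import, and 5 marker lists (pluripotent, cycling, neural progenitor, astrocyte and oligodendrocyte, and mesenchymal cells). They were drawn from general knowledge, and none was chosen on these samples.

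Shares of counts and total counts per library were compared between groups by 2-sided exact permutation tests of the difference in means, and 42 such tests were adjusted together. The smallest possible p was 0.0286 with 4 against 4 libraries, 0.00794 with 5 against 5 and 0.00216 with 6 against 6.

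Genes are named by a rule written before the data were examined. It takes the targeted gene in every group. It takes the 8 largest changes in each direction among genes with adjusted p under 0.05 in edgeR, a protein-coding name, a mean of at least 5 CPM in the higher group and no overlap between groups in CPM, where the last condition does not apply to interactions and differences. It takes up to 4 passing members with the largest changes from each list that camera called or that had 3 passing members. In the TDP-43 comparisons it also takes STMN2, UNC13A, ELAVL3, KALRN, HDGFL2 and ATG4B. Some genes that the rule names are not reported here.

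Whether sample numbers pair libraries was checked before any blocked fit was compared, by the correlation of residual log2 CPM between libraries of 1 number. For knockdown and control soma of the TDP-43 experiment each of the 3 shared numbers gave more than the limit of 0.1 (0.173, 0.288 and 0.147), so the numbers were taken to pair there. The paired (blocked) fit called 4156 genes against 4170 without the block. Knockdown neurites and soma of that experiment passed the limit too, in each of their 4 shared numbers (0.135, 0.274, 0.132 and 0.193). They meet only in the interaction, whose control pairs did not all pass, and there the paired fit called 2230 genes against 2306. In every other combination of groups at least 1 pair failed the limit. Single pairs there still reached up to 0.608, so passing it is only weak evidence of pairing.

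The comparisons, the fits, the threshold and most alternatives were fixed before the data were examined. These alternatives were RLE scaling, library sizes without TMM, no low-count filter, a filter of at least 5 CPM on average, DESeq2 1.42.0, limma-voom with sample quality weights, mitochondrially encoded genes left out, the replicate number as a block, only the compared groups in the fit, each library left out in turn, and an added limit of 2-fold. After the data were seen 4 were added: the library of 541 counts included, 7SL and ribosomal RNA genes left out, the log2 ribosomal RNA share of each library as a covariate, and the 3 neurite libraries with over 30% 7SL left out. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.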

Results

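RNA was sequenced from i3Neurons, human neurons that arise when a neurogenin-2 transgene is switched on in the induced pluripotent stem cell line WTC11. The neurons were replated on day 3 into Boyden chambers, inserts whose membrane has 1 µm pores that neurites cross and cell bodies do not, and both sides were harvested on day 17. This gives a soma fraction, which holds cell bodies and the neurites beside them, and a neurite fraction. Untreated cells gave 4 libraries per fraction. The other cells carried CRISPR interference, in which an inactive Cas9 fused to a repressor silences the gene that a guide RNA matches. In a first experiment it was aimed at HNRNPA1, with 6 knockdown and 6 non-targeting control libraries per fraction. In a second it was aimed at TARDBP, the gene of TDP-43, with 5 of each per fraction. Of the 52 libraries 51 were analysed. TDP-43 knockdown soma sample 5 held 541 counts and was left out, which left 4 in that group. In units of 1e6 counts, untreated neurite libraries held 2.54 to 4.35 and untreated soma libraries 5.21 to 10.5. Neurite and soma libraries held 6.26 to 15.0 and 8.00 to 19.4 in the HNRNPA1 experiment, and 6.83 to 14.5 and 15.7 to 28.9 in the TDP-43 experiment. Nothing says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

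Both targeted genes fell in both fractions. The product of HNRNPA1 (ENSG00000135486.19; hg38 chromosome 12, 54280193 to 54287088) binds pre-mRNA in the nucleus and regulates splicing. Its message fell in soma from 361 ± 20.7 to 141 ± 9.35 CPM (counts per 1e6; SD, n = 6 and 6) and in neurites from 590 ± 32.6 to 201 ± 15.99 CPM (n = 6 and 6). The product of TARDBP (hg38 chromosome 1, 11012344 to 11026420) binds UG-rich RNA and represses cryptic exons. Its message fell in soma from 111 ± 4.59 (n = 5) to 19.5 ± 0.927 CPM (n = 4) and in neurites from 117 ± 7.26 to 41.8 ± 4.26 CPM (n = 5 and 5). The HNRNPA1 log2 changes of −1.36 ± 0.06 (SE) in soma and −1.55 ± 0.06 in neurites had adjusted p = 6.3e-18 and 1.5e-19 (edgeR). Those of TARDBP, −2.50 ± 0.07 and −1.48 ± 0.06, had adjusted p = 8.9e-21 and 5.9e-16 (edgeR). The residual TARDBP level was 17.7% of control in soma and 36.0% in neurites. In untreated cells HNRNPA1 stood at 297 ± 25.8 CPM in soma and 1747 ± 177 in neurites, and TARDBP at 112 ± 8.54 and 86.5 ± 11.2 (SD, n = 4 each). Neither gene passed in edgeR in the experiment aimed at the other, although after TDP-43 knockdown DESeq2 called HNRNPA1 in neurites and limma-voom called it in soma. TARDBP stood at 119, 121, 142 and 137 CPM in control soma, knockdown soma, control neurites and knockdown neurites of the HNRNPA1 experiment. HNRNPA1 stood at 309, 329, 480 and 521 CPM in those of the TDP-43 experiment.

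**Figure D1:**
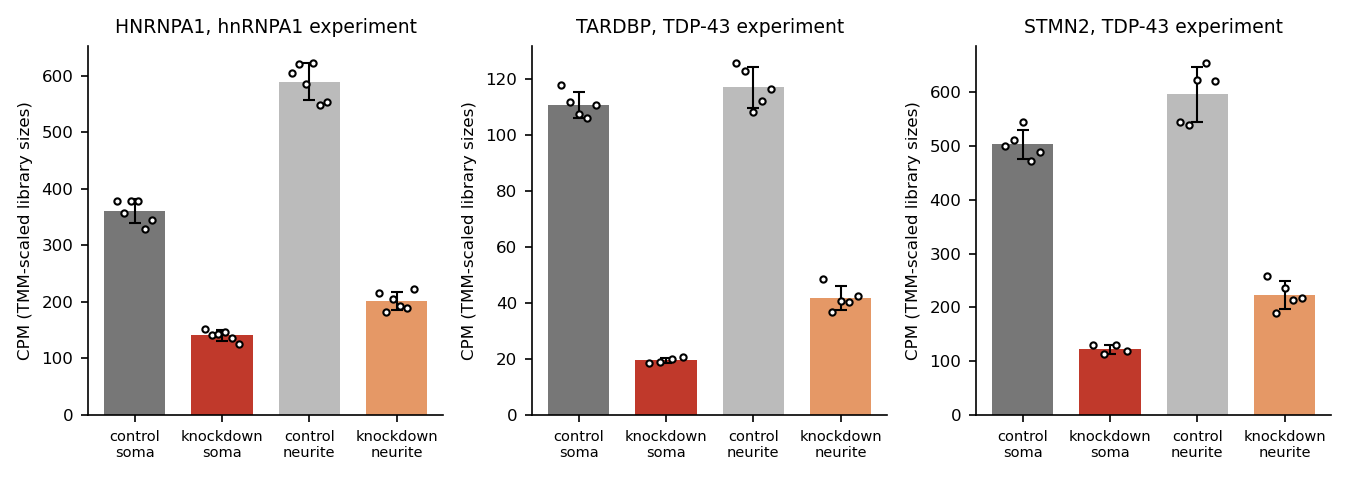
CPM of HNRNPA1, TARDBP and STMN2 in each library of the knockdown experiments (points; bars are group means with SD) by group. HNRNPA1 is lower in all 12 libraries of its knockdown than in their controls, and TARDBP in all 9 libraries of its own.

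The neurite fraction was richer in mitochondrial and ribosomal protein messages in every experiment. Messages of the 13 proteins encoded by mitochondrial DNA took 7.02 ± 1.08% of counts in untreated neurites and 2.52 ± 0.162% in soma (SD, n = 4 each), 4.48 ± 0.502 and 1.47 ± 0.284% in the HNRNPA1 controls (n = 6 each), and 2.13 ± 0.451 and 0.913 ± 0.0782% in the TDP-43 controls (n = 5 each). Cytosolic ribosomal protein messages took 5.90 ± 0.380 against 1.32 ± 0.177%, 2.34 ± 0.165 against 1.296 ± 0.0843%, and 1.95 ± 0.219 against 1.01 ± 0.0570%. No neurite library of these groups overlapped its soma group in either share. In 2-sided exact permutation tests p was 0.0286 in untreated cells, the smallest that 4 against 4 libraries can give (adjusted p = 0.05 over 42 tests, at the limit and not under it). In the same exact tests it was 0.00216 in the HNRNPA1 controls (adjusted 0.0227) and 0.00794 in the TDP-43 controls (adjusted 0.0256). Paired by sample number, which is uncertain here, exact p was 0.125 in untreated cells, 0.0313 in HNRNPA1 controls and 0.0625 in TDP-43 controls. Each is the smallest that its number of pairs can give. The cytoplasmic RNA 7SL, part of the signal recognition particle, took 1.42% of counts in untreated neurites and 10.4 and 14.1% in HNRNPA1 control and knockdown neurites. It took 27.4 and 14.4% in those of the TDP-43 experiment, where single control libraries ran from 17.2 to 45.7%. In soma it took 0.49% in untreated cells and 2.09 to 3.02% in the 4 knockdown and control groups.

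**Figure D2:**
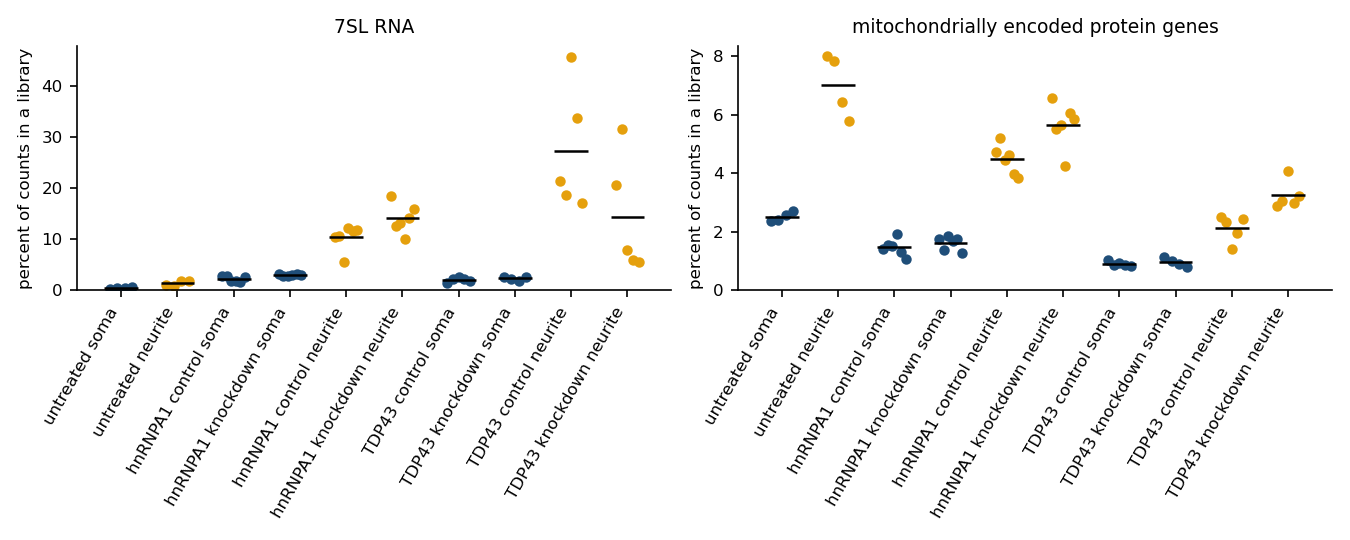
Percent of counts in 7SL and in mitochondrially encoded proteins in each library, by group. Neurite libraries lie above soma libraries in mitochondrially encoded proteins in untreated cells and both control groups. 7SL reaches 45.7% in a TDP-43 control neurite library.

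Untreated neurites against soma asked which messages neurites carry. Neurites were rich in messages for making proteins and for respiration and poor in those of stress responses. Among cytosolic ribosomal protein genes 78 of 80 were higher and none lower (78 and 1 adjusted over the list alone), with a median log2 ratio of 3.44 and RPL12 at 4.69 ± 0.15 and RPS2 leading. Of the nuclear genes for respiratory chain subunits 68 of 75 were higher and 3 lower (69 and 3 adjusted over the list alone; median 1.85), led by COX6A1 at 3.83, ATP5ME at 3.77 and COX8A at 3.74. All 13 mitochondrially encoded genes were higher (median 2.69). Translation factors and ribosome-associated proteins such as NACA (3.57), EEF1B2 (3.51) and RACK1 (3.29) followed, with 33 of 40 higher and 3 lower (median 1.241, 0.00 with library sizes). Genes of the unfolded protein and integrated stress response were lower in 22 of 31 cases and higher in 3 (median −0.73). Among them were the asparagine synthetase gene ASNS at −1.97 ± 0.29, the stress transcription factors CEBPB (−1.78) and DDIT3 (−1.53), and TRIB3 (−1.63). Of 21 interferon-stimulated genes 9 were lower and none higher (median −0.68). The median over all genes was −0.21 here and −1.43 with library sizes in place of TMM scaling, so lists are best read against that median. Genes with at least 5 counts numbered 15810 ± 2501 in untreated neurites and 38552 ± 3061 in untreated soma (SD, n = 4 each). They numbered 25592 in HNRNPA1 control soma and 26081 in TDP-43 control soma, whose libraries held more counts on average. Whether these differences in detection bear on the lower lists was not tested.

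Neurites also held the messages of their own cytoskeleton and transport machinery. Axonal cytoskeleton and growth genes were higher in 34 of 43 cases and lower in 1 (median 0.70), with the actin-binding thymosins TMSB4X (3.01) and TMSB10 (2.91) and the filament proteins NEFL (2.43) and PRPH (2.34) in front. Of 38 kinesin and dynein motor genes and adaptors 24 were higher and 1 lower (median 0.46; KIF1A 3.48, TRAK2 3.37, KIF5C 2.95). Of 45 presynaptic genes 25 were higher and 5 lower (median 0.41), led by the active zone genes RIMS1 (4.16) and RIMS2 (3.82). With library sizes these 3 medians turned to −0.54, −0.78 and −0.83, which still lies 0.90, 0.65 and 0.61 above the all-gene median. Proteasome genes were higher in 19 of 33 cases and lower in 4 (median 0.50, −0.73 with library sizes). The largest ratios belonged to AKAP12, a scaffold for protein kinase A, at 4.85 ± 0.17 (16976 against 590 CPM), and to MCF2L2 (4.75), SCLT1 (4.74), MAN1A2 (4.72), UBAP2 and SDCCAG8 (both 4.70). The lowest belonged to the calcium pump gene ATP2C2 (−2.28 ± 0.38) and the adhesion molecules CNTN6 (−2.19) and CHL1 (−2.07). How reads that map to several places were counted is not given in the sources used here. Levels of genes that share sequence with others, such as ribosomal protein genes with their pseudogenes, are therefore uncertain, and so are those of the leading genes, some of which are very high.

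In all, edgeR called 10483 of 18556 genes, 5324 higher and 5159 lower in untreated neurites (adjusted p under 0.05), and with library sizes 16965, 2041 higher and 14924 lower. With its preset correlation the camera test called 10 of 31 lists, the 8 higher and 2 lower named here, with adjusted p from 1.7e-87 (ribosomal proteins) to 0.039 (interferon-stimulated genes). None held with an estimated correlation (adjusted p = 0.14 or higher in camera). With the ribosomal RNA share of each library as a covariate, which is nearly the fraction itself (5.93% of counts in neurites, 1.43% in soma), 1380 genes were called, 1271 of them higher. The calls of ASNS, CEBPB, TRIB3, NEFL, PRPH, TMSB4X, TMSB10, ATP2C2, CNTN6 and CHL1 ended with it.

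In the controls of the knockdown experiments the same contrast gave smaller ratios of ribosomal and mitochondrial messages, together with more of several immediate early messages. Ribosomal protein genes were higher in 76 of 80 cases in both (none and 1 lower; medians 1.118 in the HNRNPA1 controls and 1.55 in the TDP-43 controls). All 13 mitochondrially encoded genes were higher (medians 1.93 and 1.77). Translation factors were higher in 27 and 25 of 40 cases and lower in 2 and 3 (medians 0.24 and 0.27, −0.11 and −0.34 with library sizes). Among immediate early and axon injury genes 13 of 24 were higher and 4 lower in the HNRNPA1 controls (median 0.44), and 15 and 6 in the TDP-43 controls (median 0.50, −0.10 with library sizes). They include the transcription factor genes NPAS4 (4.00 ± 0.22 and 4.21 ± 0.19), FOS (2.84 and 3.33) and KLF4 (3.37 and 2.68). The largest ratios also included the stress-inducible GADD45B (4.26 and 4.49), the adhesion molecule PECAM1 (3.97 and 5.22), the giant membrane-associated protein AHNAK (3.76 and 4.48) and the iodide transporter SLC5A5 (4.00 and 4.49), all under 40 CPM. Cholesterol synthesis genes were lower in 22 of 24 cases and higher in none in both controls (medians −0.55 and −0.75). Among them were MVD (−1.48 ± 0.05 in the TDP-43 controls), MVK (−0.98 in the HNRNPA1 controls) and STARD4 and DHCR7. The disulfide isomerase gene PDIA2 (−1.66 and −1.76) and the sodium channel gene SCN1A (−1.26 and −1.14) were lower in both.

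Axonal genes were higher in 20 and 19 of 43 cases and lower in 8 and 5 (median 0.11 in both, −0.25 and −0.49 with library sizes). Respiratory chain genes were higher in 39 and 42 of 76 and lower in 11 and 5 (medians 0.28 and 0.35, −0.07 and −0.28 with library sizes). In the HNRNPA1 controls neuronal transcription factors were higher in 20 of 37 cases and lower in 7, and motor genes in 15 of 39 and lower in 6 (TRAK2 2.26), with medians of 0.31 and 0.08 that turned to −0.04 and −0.28 with library sizes. In the TDP-43 controls voltage-gated channel genes were lower in 24 of 44 cases and higher in 7 (median −0.24). Markers of cycling cells were higher in 15 of 22 and 19 of 25 cases (medians 0.55 and 0.88; PLK1 1.64 and 1.74). Those of neural progenitors were higher in 8 and 6 of 15 (medians 0.44 and 0.43, 0.08 and −0.17 with library sizes; ID1 2.62 and 3.36, GLI3 1.79 and 2.66), with at most 2 lower in each. Of 19812 genes edgeR called 9582 in the HNRNPA1 controls (4657 higher), and of 22014 in the TDP-43 controls 10232 (5314 higher). With library sizes, which move the all-gene median from −0.05 to −0.40 and from −0.03 to −0.63, it called 14040 (1911 higher) and 16427 (1891 higher). The camera test called 11 and 10 lists. With an estimated correlation ribosomal proteins (adjusted p = 0.0318 and 0.031 in camera) and mitochondrially encoded proteins (0.0318 and 0.031) held in both controls, and translation factors (0.0327) and cholesterol synthesis (0.00109) in the TDP-43 controls. With an estimated correlation the others did not hold in camera (adjusted p = 0.0911 or higher). With that correlation the cycling markers were not called (adjusted p = 0.145 and 0.191 in camera), nor were the progenitor markers (0.218 and 0.384) and the immediate early genes (0.258 and 0.208).

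**Figure D3:**
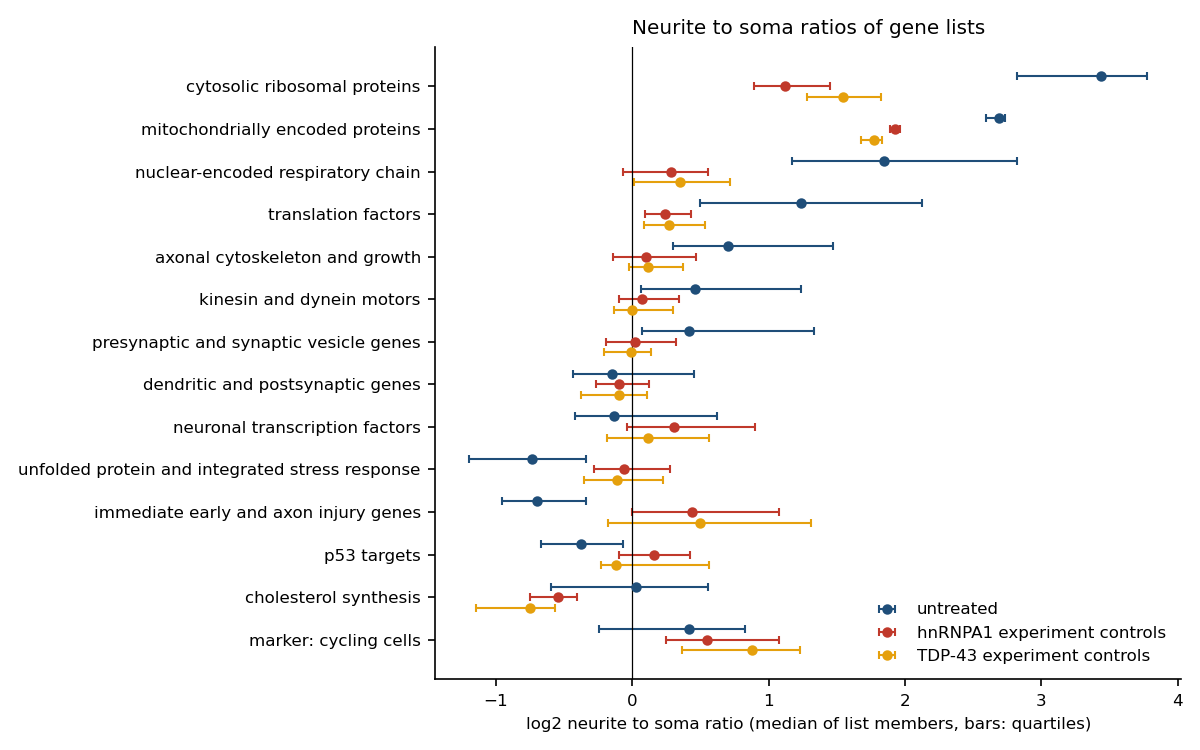
Median log2 neurite to soma ratio of each gene list (points; bars span the quartiles of the members) in untreated cells and both controls, TMM scaling. Ribosomal protein genes lie at 3.44, 1.118 and 1.55 and cholesterol synthesis genes at 0.03, −0.55 and −0.75.

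Of 15996 genes tested in all 3 experiments, 4390 were called in each, and 3955 of these had 1 direction throughout, 2349 higher and 1606 lower in neurites. With library sizes 9792 had 1 direction, 714 higher and 9078 lower. Across genes, which are not independent replicates, the log2 ratios of the 2 controls had Pearson r = 0.86 (Spearman 0.80), while untreated cells had r = 0.58 with the HNRNPA1 controls and 0.55 with the TDP-43 controls (Spearman 0.53 and 0.53). Whether the ratio differed was tested directly in edgeR. That gave 10928 genes for untreated cells against the HNRNPA1 controls (3863 with a higher ratio in untreated cells), 11048 against the TDP-43 controls (3959 higher) and 900 between the controls (468 higher in the HNRNPA1 controls, but only 27 of the 319 that differed over 2-fold). The ribosomal protein ratio was higher in untreated cells for 78 of 80 genes and lower for 1 against either control (medians 1.88 and 1.58). The respiratory chain ratio was higher for 66 of 76 and lower for 5 and 3 (medians 1.37 and 1.41). Immediate early and axon injury genes had a lower ratio in untreated cells in 21 and 20 of 26 cases and a higher one in 1 (medians −1.80 and −1.69; NPAS4 −5.33 ± 0.50 and −5.46 ± 0.51). So did 27 and 22 of 32 stress response genes, with 1 higher (medians −1.02 and −0.83; DDIT3 −2.69 and −2.92). Between the controls, cholesterol synthesis genes had a ratio higher in the HNRNPA1 controls in 6 of 24 cases and lower in none (11 adjusted over the list alone; median 0.26), and the synaptic vesicle gene SV2C (1.53 ± 0.15) and PRPH (1.46 ± 0.30) were among the highest. Untreated libraries were made with kit version 2 and all others with version 3, so kit, experiment and guide cannot be told apart. With library sizes, which put the all-gene median of the 3 differences at −1.01, −0.92 and 0.17, the counts were 16337 (1967 higher), 14770 (2287) and 1360 (1044).

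HNRNPA1 knockdown in soma asked how cell bodies respond to loss of this splicing regulator. The gene of the matrix protein tenascin C, TNC, rose by 1.698 ± 0.14 (6.4 to 20.7 CPM) and the collagen gene COL27A1 by 1.26 ± 0.11. The transcription factor genes PRDM8 (1.56 ± 0.12) and PAX6 (1.27 ± 0.11) rose too, with GFY (1.36), CNTNAP3B (1.08) and CNTNAP3C (1.07). The transcription factor gene LHX1 (−1.06 ± 0.08, 37.0 to 17.7 CPM), KLHL14 (−1.05), the calmodulin-binding PCP4 (−1.03), GUCY1A1 (−0.87) and FSTL1 (−0.85) fell. PAX6 is also a marker of neural progenitors, of which 3 of 15 rose and 1 fell (3 and 1 adjusted over the list alone), and of 12 mesenchymal markers 2 rose and 1 fell (6 and 1 adjusted over the list alone). Neither list was called (adjusted p = 0.0898 and 0.0560 in camera). HNRNPA1L3, a near copy of HNRNPA1, read −1.32 ± 0.11, and since the treatment of reads that map to several places is not given in the sources used here, this value may be that of HNRNPA1. Cholesterol synthesis genes fell in 10 of 24 cases and rose in none (16 adjusted over the list alone; median −0.23), among them STARD4 (−0.38) and HMGCS1 (−0.31). Glycolytic genes fell in 4 of 17 cases with none rising (4 adjusted over the list alone), above all the hexokinase gene HK2 (−2.54) and the aldolase gene ALDOC (−0.79). HK2 was low in soma, at 4.62 ± 2.06 CPM in controls and 0.75 ± 0.38 after knockdown (SD, n = 6 each). Neuronal transcription factors rose in 7 and fell in 4 of 37 cases (10 and 5 adjusted over the list alone; NEUROD1 0.75, INSM1 0.72). Immediate early and axon injury genes rose in 4 and fell in 1 of 24 (6 and 1 adjusted over the list alone; median 0.26; DUSP5 0.72, IER5 0.51).

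edgeR called 1404 of 19812 genes in soma, 751 higher and 653 lower, and with library sizes 1213, 494 higher and 719 lower. With the ribosomal RNA share as a covariate it called 909, and STARD4 was no longer among them. That share was 3.24 ± 0.979% in control soma and 4.44 ± 0.449% after knockdown (SD, n = 6 each). The camera test called these 4 lists and the mitochondrially encoded proteins (median 0.21, with 0 of 13 genes called by edgeR and 0 adjusted over the list alone), but with an estimated correlation none held (adjusted p = 0.397 in camera for the 4, 0.95 for the mitochondrial list).

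In neurites the knockdown moved many of the genes it moved in soma, and 784 of the 785 genes called in both fractions had the same direction. PRDM8 (1.59 ± 0.12), TNC (1.39 ± 0.11, 62.0 to 161 CPM) and PAX6 rose again, with BTN2A2 (1.56), PPP1R14A (1.32), the actin-binding TAGLN2 (1.28) and PBXIP1 (1.27). The secreted matrix protein reelin, RELN, fell from 194 to 88.4 CPM. PCP4 (−1.25), the intermediate filament gene PRPH, the serotonin receptor subunit HTR3A and GUCY1A1 fell by similar amounts. HNRNPA1L3 read −1.68 ± 0.11, with the same uncertainty as in soma. Of 13 mitochondrially encoded genes 12 rose (13 adjusted over the list alone; median 0.51), as their share of counts did, from 4.48 ± 0.502 to 5.65 ± 0.783% (SD, n = 6 each; exact permutation p = 0.0173, adjusted 0.0428; paired by sample number, exact p = 0.0938). Cytosolic ribosomal protein genes fell in 20 and rose in 1 of 80 cases (23 and 1 adjusted over the list alone; median −0.14; RPS24 −0.49), and their share fell from 2.34 ± 0.165 to 1.92 ± 0.137% (n = 6 each; exact permutation p = 0.00216, adjusted 0.0227). In the same libraries 7SL rose from 10.4 to 14.1% and ribosomal RNA from 3.61 to 5.59% of counts, which lowers every other share. Voltage-gated channel genes fell in 13 and rose in 2 of 43 cases (13 and 2 adjusted over the list alone; KCNQ5 −1.08, KCNH7 −0.50). Neuronal transcription factors rose in 14 and fell in 6 of 37 (14 and 7 adjusted over the list alone; NEUROD4 1.09), and immediate early and axon injury genes rose in 8 of 24 with none falling (11 adjusted over the list alone; FOSL2 0.75, JUND 0.55). Total counts were lower in knockdown neurites, 7.67 ± 1.152 against 11.7 ± 2.48 in units of 1e6 (SD, n = 6 each; exact permutation p = 0.00433, adjusted 0.0256). The 10 most abundant genes took more, 21.0 ± 3.58 against 15.6 ± 2.78% (SD, n = 6 each; exact permutation p = 0.0108, adjusted 0.0303; paired, exact p = 0.0625).

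edgeR called 3203 of 19812 genes in neurites, 1775 higher and 1428 lower. With library sizes, which put the all-gene median at −0.14, it called 4430, 605 of them higher, and with the ribosomal RNA share as a covariate 1175, without FOSL2. That share ran from 4.81 to 6.72% in knockdown neurites and from 2.31 to 4.47% in control neurites, without overlap. Effects of the knockdown and of this library difference can therefore hardly be told apart in neurites. KCNQ5 was not called with the covariate, in limma-voom or without the low-count filter. In camera these 5 lists were called and none held with an estimated correlation (adjusted p = 0.63 or higher in camera).

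Whether HNRNPA1 knockdown changed a gene's neurite to soma ratio was tested directly, and few genes passed: 35 in edgeR, 9 with a higher ratio after knockdown and 26 with a lower one, where 1800 had an unadjusted p under 0.05. Higher were the small GTPase gene RHOC (0.81 ± 0.18), TGFB1 (0.69 ± 0.14), PLCH2 (0.66), the sterol regulator SREBF1 (0.52 ± 0.10), SHMT2 (0.40) and the hexokinase gene HK2 (2.75). Lower were SV2C (−0.75 ± 0.14), TXNIP (−0.70 ± 0.11), the retinoic acid binding protein CRABP1 (−0.68 ± 0.11), the nuclear receptor ESRRG (−0.67), UNC13C (−0.61) and ID2 (−0.52). HNRNPA1 itself did not pass (−0.19 ± 0.08, adjusted p = 0.46 in edgeR). In camera 10 lists were called, among them cholesterol synthesis (median 0.22; 0 of 24 genes called by edgeR, 6 adjusted over the list alone) and ribosomal proteins (median −0.15; 0 of 80 called by edgeR and 0 adjusted over the list alone), and none held with an estimated correlation (adjusted p = 0.29 or higher in camera) or passed in fry. The count was 12 without knockdown neurite sample 2, 73 without control soma sample 3, 77 in DESeq2, where the same test was run, and 71 with library sizes, 7 of them higher. RHOC, TGFB1, SREBF1 and SHMT2 were not called with library sizes.

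TDP-43 knockdown in soma asked how cell bodies respond to loss of this repressor of cryptic exons. Of 26 genes known to be spliced cryptically when TDP-43 is lost, a list not chosen on these samples, 16 fell and 4 rose (17 and 6 adjusted over the list alone; median −0.34). STMN2 (hg38 chromosome 8, 79610814 to 79666175), which encodes the axon growth protein stathmin-2 and is cut short by a cryptic exon when TDP-43 is lost, fell from 503 ± 26.9 to 123 ± 8.31 CPM (SD, n = 5 and 4), a log2 change of −2.04 ± 0.08. The neuronal RNA-binding protein gene ELAVL3 fell by 1.55 ± 0.06, the insulin receptor gene INSR by 1.49, ATG4B by 0.52 ± 0.06 and the synaptic gene UNC13A (hg38 chromosome 19, 17601328 to 17688365) by 0.37 ± 0.07. KALRN (−0.16 ± 0.07, adjusted p = 0.11 in edgeR, though called at −0.195 when paired by sample number) and HDGFL2 (0.08 ± 0.06, adjusted p = 0.40 in edgeR) did not pass. In the HNRNPA1 experiment STMN2 read 738 and 720 CPM in control and knockdown soma.

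Outside that list, the major vault protein gene MVP rose from 5.8 to 75.1 CPM (3.70 ± 0.10). The exchange factor gene PREX2 (2.60), the transcription factor NFIB (2.15), the protease TLL1 (2.52), COL27A1 (2.41) and the chemokine receptor ACKR1 (2.12) rose too. The receptor phosphatase gene PTPRT (−2.19 ± 0.07, 224 to 49.0 CPM), the cadherin gene CDH4 (−2.13), KLHL14 (−2.08), C1QL3 (−2.01) and the transcription factor TFAP2A (−1.83) fell. MASP2 read −2.60 ± 0.12, but it ends 102 bases beyond the end of TARDBP on the other strand. Whether the counting used strand is not given in the sources used here, so its reads and those of TARDBP cannot be told apart. Genes of endoplasmic reticulum translocation and secretion rose in 13 of 48 cases with none falling (18 and 1 adjusted over the list alone; median 0.12; RPN1 0.38, TMED9 0.28). Stress response genes rose in 10 and fell in 1 of 32 (13 and 1 adjusted over the list alone; the cystine transporter gene SLC7A11 1.01, PHGDH 0.72). Nuclear noncoding RNAs rose in 5 of 8 cases (6 adjusted over the list alone; median 0.32; PVT1 0.47, NEAT1 0.40, MALAT1 0.31), and their share of counts from 0.143 ± 0.0134 to 0.172 ± 0.00435% (SD, n = 5 and 4; exact permutation p = 0.0159, adjusted 0.0417). Paired over the 3 shared sample numbers that share rose by 0.0273 points, with an exact p of 0.25, the smallest that 3 pairs can give. Of 43 axonal genes 6 fell and none rose (4 adjusted over the list alone; TUBB4A −0.42, MAPT −0.32 beside STMN2). edgeR called 4170 of 22014 genes, 2072 higher and 2098 lower, and 1677 with library sizes. UNC13A, RPN1, TMED9, PVT1, NEAT1, MALAT1, TUBB4A and MAPT were not called with library sizes. The camera test called these 5 lists, and with an estimated correlation the cryptic splicing list held (adjusted p = 0.0118 in camera) while the others did not (0.80 or higher).

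In neurites the cryptic splicing list had 14 of 26 genes lower and 5 higher (14 and 6 adjusted over the list alone; median −0.26), but unlike in soma it was not called with an estimated correlation (adjusted p = 0.108 in camera). STMN2 fell from 596 ± 51.4 to 223 ± 25.6 CPM (SD, n = 5 each; −1.42 ± 0.07), INSR by 1.08, PFKP by 0.90, UNC13A by 0.77 ± 0.07, ELAVL3 by 0.77 ± 0.06, ATG4B by 0.65 ± 0.06 and KALRN by 0.25 ± 0.07, and the synapse organiser AGRN rose by 0.80, while HDGFL2 did not pass (0.15 ± 0.06, adjusted p = 0.074 in edgeR). STMN2 read 823 and 785 CPM in control and knockdown neurites of the HNRNPA1 experiment. ACKR1 (2.56 ± 0.12), TMEM179 (2.42 ± 0.11, 7.3 to 39.3 CPM), MVP (2.21 ± 0.12), NKD2 (2.10), the transcription factors ELK1 (1.76) and TLX1 (1.74) and the growth factor IGF2 (1.73) rose most. PTPRT (−1.57 ± 0.07), the galanin receptor GALR1 (−1.46), TNC (−1.31) and CDH4 (−1.26) were among the largest falls with TARDBP and STMN2, beside MASP2 (−1.38), which adjoins TARDBP. Endoplasmic reticulum translocation and secretion genes rose in 34 of 48 cases and fell in none (34 adjusted over the list alone; median 0.28), led by STT3A (0.74), SSR1 (0.67) and SEC61A1 (0.60). Cholesterol synthesis genes rose in 14 of 24 cases with none falling (14 adjusted over the list alone; median 0.22; SREBF2 0.63). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; median 0.56), and their share of counts from 2.13 ± 0.451 to 3.25 ± 0.476% (SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0256), beside a fall of 7SL from 27.4 to 14.4% that raises every other share. Ribosomal protein genes rose in 39 of 80 cases and fell in none (46 adjusted over the list alone; median 0.26), though their share, 2.52 ± 0.498 against 1.95 ± 0.219%, did not pass after adjustment (exact permutation p = 0.0476, adjusted 0.0741). Translation factors rose in 22 and fell in 3 of 40 cases (25 and 3 adjusted over the list alone; EIF4G1 0.45, EIF4A1 −0.44).

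Among messages of neuronal function in neurites, motor genes rose in 16 and fell in 2 of 39 cases (TRAK2, which ties mitochondria to motors, 1.68), and dendritic and postsynaptic genes in 20 and 7 of 43 (HOMER2 0.59, CAMK2B −0.65). Voltage-gated channel genes rose in 15 and fell in 6 of 44 cases (KCNT1 0.94, SCN1A −0.72) and neuronal transcription factors in 13 and 4 of 35 (BCL11B 1.03, TBR1 −1.05). Adjusted over the list alone these counts were 16 and 3, 20 and 7, 17 and 6, and 14 and 4. Stress response genes rose in 10 of 32 cases with none falling (10 adjusted over the list alone) and respiratory chain genes in 13 of 76 with 1 falling (12 and 1 adjusted over the list alone). edgeR called 5470 of 22014 genes, 3075 higher and 2395 lower. With library sizes it called 2580, 1792 higher, with the replicate number as a block 1882, and with the ribosomal RNA share as a covariate 3082. That share was 3.67 ± 0.379% in control and 4.88 ± 0.627% in knockdown neurites (SD, n = 5 each). KALRN was not called with library sizes, and BCL11B and TBR1 not with that covariate, which EIF4A1 failed as well. In camera these 12 lists were called, and none held with an estimated correlation. With an estimated correlation secretion genes had adjusted p = 0.0908 in camera and cholesterol synthesis and cryptic splicing 0.108. Mitochondrially encoded proteins, ribosomal proteins and the rest were not called either with it (adjusted p = 0.275, 0.652 and 0.123 or higher in camera).

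The effect of TDP-43 knockdown differed between fractions for 2306 genes in edgeR, 1278 with a higher and 1028 with a lower neurite to soma ratio after knockdown. Of the 471 that differed over 2-fold 77 were higher and 394 lower. TARDBP itself was among them (1.02 ± 0.09), with a smaller fall in neurites than in soma. STMN2 (0.62 ± 0.11) and ELAVL3 (0.78 ± 0.09) moved in the same way, while UNC13A (−0.40 ± 0.10, adjusted p = 0.012 in edgeR) fell more in neurites. KALRN, HDGFL2 and ATG4B (−0.09, 0.07 and −0.13) did not differ beyond the spread. The ratio rose for NKD2 (2.05 ± 0.18), the histone demethylase PHF2 (1.52) and the motor adaptors TRAK2 (1.37) and BICD2. It fell for COL27A1 (−1.56 ± 0.28), GNG8 (−1.51), MVP (−1.49 ± 0.16) and PTPRQ (−1.40). It rose in 14 of 43 dendritic and postsynaptic genes (GRIN2B 0.97, SHANK1 0.64) and 13 of 44 voltage-gated channel genes (KCND3 0.85, KCNC4 0.75). It also rose in 12 of 24 cholesterol synthesis genes (STARD4 0.72, MVD 0.61; median 0.25), 11 of 39 motor genes and 9 of 13 mitochondrially encoded genes, and fell in no member of these lists. Adjusted over the list alone the counts were 19 (and 1 falling), 23 (and 2 falling), 14, 11 and 13. Nuclear noncoding RNAs had a lower ratio in 5 of 8 cases (6, and 1 higher, adjusted over the list alone; KCNQ1OT1 −0.75, NEAT1 −0.45). In camera 16 lists were called, and none held with an estimated correlation (adjusted p = 0.0697 in camera for cholesterol synthesis, 0.185 or higher for the others). With library sizes 328 genes were called, 130 of them higher, and with the ribosomal RNA share as a covariate 374. No mitochondrially encoded gene was called by edgeR in either. STMN2, UNC13A, SHANK1, KCNQ1OT1 and NEAT1 were not called with library sizes, and SHANK1, NEAT1 and KCNC4 not with the covariate. The TDP-43 controls enter this interaction and also the difference between the controls, which holds no knockdown library. There STARD4 (0.75), MVD (0.56) and TRAK2 (0.61) also had a lower ratio in the TDP-43 controls than in the HNRNPA1 controls. So did UNC13A (0.41) and KALRN (0.49), which do not rise in the interaction. How much of the interaction comes from these control libraries was not tested.

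**Figure D4:**
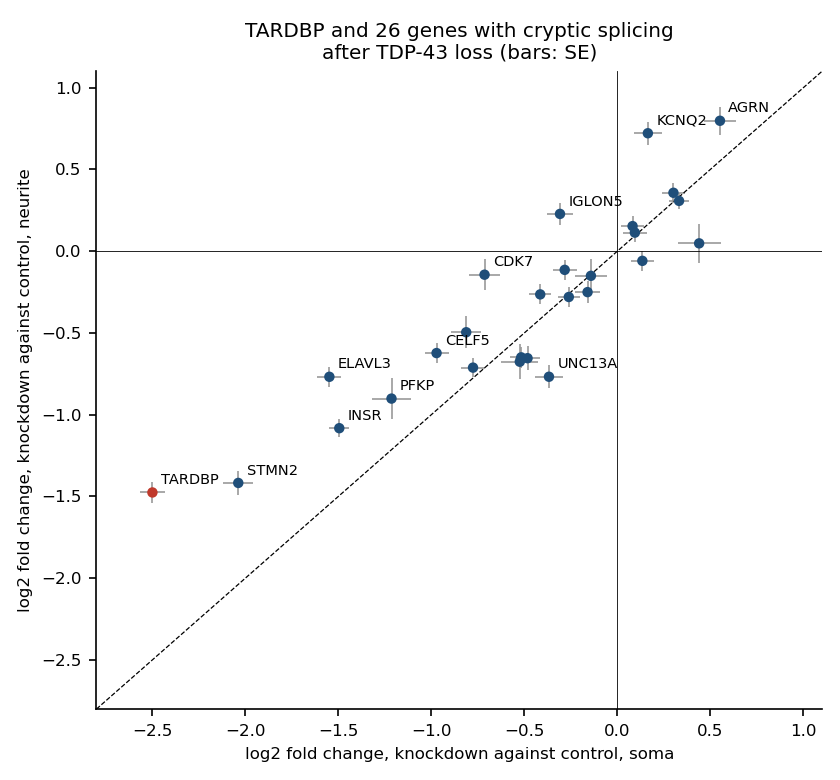
Log2 change after TDP-43 knockdown in soma (x axis) and neurites (y axis) of TARDBP and 26 genes known to be spliced cryptically after TDP-43 loss (bars are SE). TARDBP, STMN2 and ELAVL3 lie above the diagonal, with changes of −2.50 and −1.48, −2.04 and −1.42, and −1.55 and −0.77.

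The knockdown effects, each against its own controls, differed from each other for 2908 genes in soma (1400 with a higher value in the HNRNPA1 knockdown) and 3855 in neurites (1459 higher) of 22890 tested in edgeR. TNC, which rose with HNRNPA1 knockdown and fell in neurites with TDP-43 knockdown, differed by 3.65 ± 0.28 in soma and 2.69 ± 0.19 in neurites. The soma difference exceeds the rise of TNC in HNRNPA1 knockdown soma (1.698 ± 0.14), so TNC read lower in TDP-43 knockdown soma as well. CDH4 (2.22 ± 0.13) and GALR1 (2.21) differed in the same direction in soma. MVP (−3.34 ± 0.17), PREX2 (−2.39) and LHX1 (−1.89) in soma and ACKR1 (−2.64 ± 0.21), TMEM179 (−2.57) and LHX1 (−2.19) in neurites went the other way. The cryptic splicing list differed in 19 of 26 genes in soma, 16 of them higher in the HNRNPA1 knockdown (16 and 3 adjusted over the list alone; STMN2 2.00 ± 0.10, ELAVL3 1.54 ± 0.09). In neurites ribosomal protein genes had a lower value in the HNRNPA1 knockdown in 45 of 80 cases and a higher one in none (57 adjusted over the list alone; median −0.43). The same held for secretion genes in 28 of 48 cases, translation factors in 17 of 40, motor genes in 12 of 39 and cholesterol synthesis genes in 11 of 24, with no member higher. Adjusted over the list alone the lower counts were 30, 19, 16 and 12, and 1 translation and 3 motor genes were higher. In soma 487 genes were called in both knockdowns, where independent sets of these sizes would share 282.6 in either direction. Of the 487 genes 312 had the same direction. In neurites 1199 were called in both, against 851.7 for independent sets, and 748 of the 1199 had the same direction. With library sizes, which put the all-gene median at −0.20 in neurites, the counts were 1293 in soma and 3907 in neurites, 459 of these higher.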

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

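The tests of 7SL, of soma RNA in the control neurites and of the markers were chosen after the results they bear on were seen. The tests of soma and control RNA in the TDP-43 interaction and the regrouping of libraries were fixed before.

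Single libraries stood apart from their group in 7 of 160 groups of values, against 8 expected by chance at 1 in 20. HNRNPA1 control neurite sample 3 had 5.55% 7SL and 10.19% of counts in its 10 most abundant genes, low for that group, and sample 4 had 900.2 CPM of STMN2, high for it. Untreated soma sample 7 had 1.768% ribosomal RNA and 4.813% of counts in its 10 most abundant genes, both high for the group. In TDP-43 knockdown neurites sample 3 had 4.074% mitochondrially encoded messages, high for the group, and sample 2 0.062% nuclear noncoding RNAs, low for it.

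Differences between groups stood out by their own test in edgeR. The effect of HNRNPA1 knockdown differed between fractions for 35 genes and that of TDP-43 knockdown for 2306. The 2 knockdowns differed for 2908 genes in soma and 3855 in neurites. The neurite to soma ratio differed for 10928 genes between untreated cells and HNRNPA1 controls, 11048 between untreated cells and TDP-43 controls, and 900 between the controls. Among named genes HNRNPA1 knockdown raised the ratio of RHOC (0.81), BTBD17 and TGFB1 (0.69 each), PLCH2 (0.66), PPP1R14C (0.55), SREBF1 (0.52) and SHMT2 (0.40). It lowered that of SV2C (−0.75), TXNIP (−0.70), CRABP1 (−0.68), ESRRG (−0.67), UNC13C (−0.61), ADRA1A (−0.56), ATRNL1 and ID2 (−0.52 each). TDP-43 knockdown raised the ratio of NKD2 (2.05), PHF2 (1.52), TRAK2 (1.37), MLYCD (1.233), MASP2 (1.216), PDZRN4 (1.183), ICAM5 (1.168), BICD2 (1.112), TARDBP (1.02), ELAVL3 (0.78) and STMN2 (0.62). It lowered that of COL27A1 (−1.56), GNG8 (−1.51), MVP (−1.49), PTPRQ (−1.40), ACSM6 and CEP112 (−1.26 each), PDE9A (−1.181), MC1R (−1.178) and UNC13A (−0.40).

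The TDP-43 interaction of 2306 genes could arise if knockdown and control neurite libraries held different shares of soma RNA. Interaction values would then follow the neurite to soma ratio of untreated cells, and over 2033 genes, which are not independent replicates, the Spearman correlation was 0.292 (95% interval 0.247 to 0.335, across the limit of 0.3 set beforehand), so this stays open. Control RNA mixed into knockdown neurites would have to make up 22.2% to leave the residual TARDBP, which would lower the ratio of the 16 genes raised over 4-fold in soma by 0.362. Their median was −0.954 (95% interval over genes −1.25 to −0.722), and leaving out −0.362 was the limit set beforehand against mixing. The 16 genes were picked by their soma change in the same fit, which enters the interaction and can pull their values down. The interval also resampled genes and not libraries, so mixing of control RNA stays open. Without the 3 neurite libraries with over 30% 7SL 2385 genes were called, which argues against these 3 libraries as the cause. In the neurite libraries left, 7SL still took 17.2 to 21.4% in controls and 5.65 to 20.6% after knockdown, so its share in general stays open. A difference in how neurites and soma respond was not tested apart from these and stays open too. Whether ratios peculiar to the TDP-43 control libraries contribute was not tested either. With library sizes, which count 7SL, 328 genes were called and with the ribosomal RNA share as a covariate 374, and the cause of these losses was not tested.

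Ratios of ribosomal protein and respiratory chain genes were smaller in both controls than in untreated cells, which more soma RNA in the control neurite libraries could bring. Of all genes whose ratio differed, most (7065 of 10928 and 7089 of 11048) had a higher one in the controls. The share of soma RNA that the ribosomal protein medians need sets a floor, its log2, under the ratio of any gene, and genes called at a log2 ratio under −2 with library sizes in untreated cells were held to it. Over 1460 such genes the median minus that floor was −0.171 in HNRNPA1 controls (95% interval over libraries −0.213 to −0.0180; share 78.2%), which argues against mixing as the whole cause, though narrowly and only if both kit versions capture these genes alike, and 0.223 over 1439 genes in TDP-43 controls (−0.0241 to 0.784; share 61.4%), which leaves it open. A first version, with 7SL and ribosomal RNA in the library sizes, gave −0.360 (−0.436 to −0.194) and −0.569 (−0.822 to −0.304). It was changed so that 7SL and ribosomal RNA would not count toward the library sizes, and the effect of each alone was not tested. Library kit version stays open, since 0 experiments hold both versions, and no biological account was tested.

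Markers of cycling cells (15 of 22 and 19 of 25) and some of progenitor cells (8 and 6 of 15) were called higher in control neurites, though neither list held with an estimated correlation (adjusted p = 0.145 and 0.191, and 0.218 and 0.384, in camera). Whole neuronal somata in the neurite chamber could bring no gene above its share in soma. Yet with library sizes 8 of 22 cycling markers in HNRNPA1 controls and 8 of 25 in TDP-43 controls were called higher, which argues against whole somata. Nuclei alone may hold other shares of messages than the soma fraction, so these counts cannot decide on nuclei, which stay open. Cells of another type in the neurite chamber would bring all their abundant messages. Of the 6 most abundant progenitor and mesenchymal markers 2 were higher in both controls (NES, 1.07 and 0.91, and DLL1, 0.90 and 0.80), THY1 was lower (−0.39 and −0.34), and their medians were 0.0176 in HNRNPA1 controls and −0.0176 in TDP-43 controls, so this stays open. Whether neurites themselves hold these messages was not tested.

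Other groupings of the libraries were compared with the real one by refitting after libraries were regrouped. In untreated cells 1 of 35 splits, the real one, gave as many genes, which is the smallest share possible there, and the highest other split gave 0 genes against 10483. Of 100 splits 1, the real one, gave as many in HNRNPA1 controls (9582, highest other 5892), TDP-43 controls (10232, 2593), HNRNPA1 knockdown in soma (1404, 862) and neurites (3203, 933), TDP-43 knockdown in soma (4170, 2357) and neurites (5470, 984) and its interaction (2306, 1480). The same held in 50 splits for the difference between knockdowns in soma (2908, 1950) and neurites (3855, 3137). For the HNRNPA1 interaction 3 of 100 splits, the real one included, gave at least its 35 genes and the highest gave 1076. Splits for the HNRNPA1 and TDP-43 interactions regrouped knockdown and control libraries separately in each fraction. They therefore also break up the knockdown effect that soma and neurites share, or can set it against itself. Splits for the difference between knockdowns likewise break up each knockdown effect. For these interactions and differences the splits cannot decide on chance, and no conclusion is drawn from them.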

How the results depend on the processing

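The alternatives with ribosomal RNA or 7SL, and the one with the library of 541 counts, were chosen after the data were seen. For the counts of genes called, RLE scaling, mitochondrially encoded genes left out, 7SL and ribosomal RNA genes left out, the library of 541 counts included and only the compared groups in the fit left every count within 1.5 times the reported one. The cause was not tested for any of the changes given here.

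With library sizes alone the counts were 16965 in untreated cells, 16427 in TDP-43 controls, 1677 and 2580 for TDP-43 knockdown in soma and neurites, 328 for its interaction, 71 for the HNRNPA1 interaction, 1293 for the difference between knockdowns in soma, 1360 for the difference between controls, and 9792 genes shared in direction by all 3 experiments. With the ribosomal RNA share as a covariate they were 1380 in untreated cells, 909 and 1175 for HNRNPA1 knockdown in soma and neurites, 63 for its interaction, 3082 for TDP-43 knockdown in neurites and 374 for its interaction. With an added 2-fold limit, which can only lower a count, they were 5567, 1504 and 2448 for the 3 fraction contrasts, 89, 158 and 2 for HNRNPA1 knockdown in soma, neurites and the interaction, and 447, 741 and 471 for TDP-43 knockdown. The HNRNPA1 interaction gave 140 without a filter, 77 in DESeq2, 62 in limma-voom and 55 with the replicate block. A filter of at least 5 CPM, which tests fewer genes, gave 7309 for untreated cells against TDP-43 controls, and limma-voom gave 2223 for the difference between controls.

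With the replicate number as a block, TDP-43 knockdown in neurites gave 1882, and the other blocked (paired) counts were 10842 in untreated cells, 9867 and 10028 in the controls, 1393 and 3634 for HNRNPA1 knockdown, 4156 for TDP-43 knockdown in soma and 2230 for its interaction. In TDP-43 knockdown against control soma, where the numbers were taken to pair, the block added calls of KALRN and, in camera, of presynaptic genes (adjusted p = 0.0370), dendritic and postsynaptic genes (0.0280) and RNA granule proteins (0.0309), all lower. With an estimated correlation, which was run without the block, these 3 lists were not called (adjusted p = 0.982 each). It changed no other call of a named gene or a list there. Residual correlations of the 4 untreated soma and neurite pairs were 0.086, 0.127, 0.213 and 0.079, each library closest to the one of its own number, which hints at pairing without passing the limit of 0.1.

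Leaving out 1 library at a time gave 8709 to 10402 genes in untreated cells, 8869 to 9765 and 9289 to 10315 in the controls, 997 to 1539 and 2243 to 3487 for HNRNPA1 knockdown in soma and neurites, 3237 to 4710 and 4697 to 5471 for TDP-43 knockdown, 1638 to 2484 for its interaction, and 12 to 73 for the HNRNPA1 interaction. For the last, the count moved more than 1.5 times without knockdown neurite samples 2, 4, 5 or 6, knockdown soma samples 1, 2, 4, 5 or 6, control neurite samples 1, 2 or 4, or control soma samples 2, 3, 5 or 6.

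For gene lists, the estimated correlation kept 202 results and weakened 77, fry kept 216, strengthened 43 and weakened 16, and the block kept 269. Of the lists that camera called, all 10 passed fry in untreated cells, all 11 in HNRNPA1 controls and all 10 in TDP-43 controls. With HNRNPA1 knockdown 4 of 5 passed in each fraction and 0 of 10 in the interaction. With TDP-43 knockdown all 5 passed in soma, 11 of 12 in neurites and 13 of 16 in the interaction. Fry does not set a list against other genes. In fry 4 lists in untreated cells took the direction opposite to that of camera: neuronal transcription factors (adjusted p = 0.00715), dendritic and postsynaptic genes (0.0217), RNA granule proteins (0.0254) and cycling markers (0.0277). The first 3 have a median below 0 and a mean above it, since a few members are far higher in neurites. Of the share results without single libraries 368 were kept and 69 weakened, and of the paired ones 14 and 4. Most of the 69 were in untreated cells, where 3 against 4 libraries cannot pass the exact test used here, which doubles the smaller tail.

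For the interactions, simulated 2-fold changes were found in 74.6% of cases in counts like those of the HNRNPA1 experiment and in 71.6% in counts like those of the TDP-43 experiment, so some changes of this size are missed.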

Other observations

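No hypothesis beyond the comparisons of the report was tested in this part. In HNRNPA1 controls 11 of 26 p53 targets were higher in neurites and 2 lower (11 and 2 adjusted over the list alone; median 0.16, −0.19 with library sizes), with the cell cycle inhibitor CDKN1A at 2.69 ± 0.16 and the cell death gene PMAIP1 also higher. In TDP-43 controls 8 were higher and 6 lower, with CDKN1A at 3.74 ± 0.20, and in untreated neurites 2 of 24 were higher and 9 lower (median −0.37). The list was not called by camera in any of these (adjusted p = 0.066, 0.59 and 0.11). HNRNPA1 knockdown neurites had more of the cell death gene BBC3 (0.85 ± 0.13, edgeR adjusted p = 2.2e-05).

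Other lists were not called by camera in untreated neurites against soma (adjusted p = 0.063 or higher). Higher in more members than lower were mitochondrial ribosomal proteins (36 and 11 of 71, median 0.58, −0.64 with library sizes), glycolytic enzymes (10 and 2 of 17, median 0.54, −0.70 with library sizes), secretion genes (25 and 9 of 48, median 0.34, −0.89), nuclear pore and import genes (21 and 4 of 41, median 0.24, −0.99), hnRNP genes (11 and 5 of 27, median 0.20, −1.05) and the genes with cryptic splicing (10 and 5 of 26, median 0.11). So were cycling markers (10 and 2 of 24, median 0.42), progenitor markers (4 and 0 of 9, median 0.55) and pluripotency markers (1 and 0 of 9, median 0.06). Lower in more were SR splicing factors (12, and 3 higher, of 24, median −0.24), RNA granule proteins (22 and 18 of 55, median −0.03), nuclear noncoding RNAs (5 and 1 of 9, median −0.39), immediate early genes (12 and 1 of 20, median −0.70), autophagy and lysosome genes (15 and 12 of 42, median −0.07), neuronal transcription factors (9 and 7 of 33, median −0.13), mesenchymal markers (4 and 0 of 13, median −0.48) and astrocyte and oligodendrocyte markers (2 and 0 of 10, median −0.25). Near balance were channels (12 and 12 of 43), dendritic and postsynaptic genes (14 and 13 of 42, median −0.15) and cholesterol synthesis genes (9 and 8 of 24, median 0.03). In HNRNPA1 itself, a member of the hnRNP list, the ratio was 2.56 ± 0.12 in untreated cells, 0.71 ± 0.06 in HNRNPA1 controls and 0.64 ± 0.06 in TDP-43 controls, the last near 0 (0.02) with library sizes.

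CBX5, a chromatin gene chosen after its values were seen, starts 59 bases from HNRNPA1 on the other strand. It fell by 0.23 ± 0.05 in soma and 0.30 ± 0.05 in neurites after HNRNPA1 knockdown (edgeR adjusted p = 0.007 and 2.2e-04), less than HNRNPA1 itself at −1.36 and −1.55, and the soma call ended with the ribosomal RNA share as a covariate (−0.18, adjusted p = 0.0615). It did not fall after TDP-43 knockdown (0.08 in soma and 0.25 in neurites). Whether the repressor reaches both start sites was not tested.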
